A study of Homo sapiens with 6 samples.

How the data were processed

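RNA was measured by poly(A)-selected mRNA sequencing in 6 libraries of MIA PaCa-2, an established human cell line from a pancreatic ductal carcinoma. Per the labels, 3 libraries came from untreated cells and 3 from cells kept with 10 nM triptolide for 24 h. The series' design text calls the triptolide libraries a control group, and the groups here follow the treatment label of each sample. The labels give pancreas as the tissue and as the source of the extracted RNA, beside the name of the cell line. The labels' protocols describe oligo(dT) capture, random-hexamer priming and paired reads of 150 bp on 1 of 2 sequencer models, without saying which library went to which. They do not say whether strand was kept. The labels do not say that the 3 libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

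The deposited table holds whole-number counts per Ensembl gene, which the authors did not normalize as far as the values show. HISAT2 and featureCounts are named, per the submitters' processing notes, with no versions. The genome build, the annotation release, the strand setting and the treatment of reads that fit several genes are not given in the sources used here, so no coordinates are printed. Without the strand setting, reads of a gene and of its antisense partner cannot be told apart, and counts of near-identical gene copies or overlapping genes are uncertain. The table has 35716 genes, and 35639 of the IDs were matched to gene names by ID. Gene types and GC content were taken from GENCODE 29, and 99.2% of the tested genes had a GC value.

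Total counts ranged from 16302961 to 23262713 per library. Genes were kept by edgeR's filterByExpr, which left 15202. They were scaled by TMM and tested with edgeR 4.0.16 (glmQLFit and glmQLFTest) in R 4.3.3, with the 2 groups as the only term and Benjamini-Hochberg adjustment over all genes tested. A gene is said to have risen or fallen at an adjusted p under 0.05. Standard errors of log2 fold changes were taken from the size of the fold change and its F statistic. CPM values use the TMM-scaled library size and are given as mean ± SD over the 3 libraries of a group. For a gene with 3 counts or fewer in a group of 3 libraries, the fitted fold change is not used. With 0 counts the fold is a bound against a floor of 3 counts over the group, and with 1 to 3 counts it is a ratio with a 95% exact interval. Such intervals cover counting error only, since reads without molecular identifiers are not independent molecules.

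Before the data were examined, 31 gene lists, the tests, most alternatives and the rule for named genes were fixed. The rule took the 8 genes with the largest fold change in each direction among those past the threshold, with a mean of at least 5 CPM and no overlap between groups. It added a fixed set of genes named for triptolide, autophagy, matrix and survival, and from each list up to 3 members per direction with the smallest adjusted p, or the 2 most abundant where none passed. Some genes that the rule takes are not reported here. Lists with at least 5 tested members, 30 of them, were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the lists. Camera with an estimated correlation and fry were run beside it. Counts of members were also adjusted over each list alone. Another 4 lists were written after the top of the results had been seen: placental trophoblast genes, blood, stromal and vascular genes of placenta, fibroblast and mesenchymal genes, and hnRNP, SR and core spliceosome genes. They were not tested as sets. Shares of counts were compared with exact two-sided permutation tests, whose smallest possible p with 3 against 3 libraries is 0.1.

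The alternatives were RLE size factors, library totals alone, scaling on ribosomal protein genes, no low-count filter, a mean of at least 5 CPM, DESeq2 1.42.0, limma-voom, a block for the replicate number, glmTreat against a fold of 1.5, and each library left out in turn. A GC offset per library and counts without the genes of the placental, blood and fibroblast lists were added after seeing the data. The fit was tested on simulated data for triptolide against untreated cells, in which 14883 genes were tested and 50 genes were changed at each of 4 fold sizes. It recovered 18% of the genes changed by 1.5-fold, 84% of those changed by 2-fold and 98% of those changed by 4-fold, with 8 calls among unchanged genes. Simulated counts were drawn independently for each gene, with dispersions estimated from these libraries. The changed genes excluded the least abundant ones and were far fewer than the genes called in the data. These shares need not hold for the data. Figures were drawn with matplotlib 3.10.9.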

Results

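Gene expression was compared between MIA PaCa-2 cells kept in medium alone and cells kept with triptolide, a diterpenoid from Tripterygium wilfordii that binds the XPB subunit of the transcription factor TFIIH, at 10 nM for 24 h. The series title places the comparison in the setting of autophagy and the extracellular matrix. Each group had 3 libraries. The untreated libraries held 17566458, 18215007 and 19600354 counts and the triptolide libraries 16302961, 22549382 and 23262713. No pair of libraries agreed within sampling noise. The chi-square over degrees of freedom was 5.46 between untreated replicates 1 and 2, and 45.9 and 33.7 between these and untreated replicate 3. It ran from 29.1 to 70.3 within the triptolide group and from 31.2 to 88.2 between groups, so that the ranges overlapped. The first principal component, with 61.4% of the variance, separated the groups.

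In cells with triptolide, POLR2A (ENSG00000181222), the largest subunit of RNA polymerase II, rose from 257 ± 50.3 to 1758 ± 428 CPM (SD, n = 3 libraries each), a log2 fold change of 2.78 ± 0.23 (SE) with an edgeR adjusted p of 2.27e-05. The immediate early gene FOSB (ENSG00000125740) rose 10.5-fold, from 1.44 ± 0.22 to 15.2 ± 1.79 CPM. The histone gene H2BC21 (ENSG00000184678) rose 7.39-fold and the inducible heat shock gene HSPA1A (ENSG00000204389) rose 2.62-fold. The chemokine genes CXCL8 (ENSG00000169429) and CXCL1 (ENSG00000163739) fell 2.8-fold and 2.44-fold. The RNA-binding protein gene HNRNPDL (ENSG00000152795) fell 3.36-fold, from 308 ± 26.4 to 91.7 ± 8.2 CPM, with an adjusted p of 4.9e-05. The matrix genes THBS1, COL1A1 and FN1 fell, and genes known from placenta had the largest rises among genes with a mean of at least 5 CPM. Markers of other cell types are given beside both of these groups. Of 58 tested genes on a list of fibroblast and mesenchymal genes, 27 fell, 6 rose and 25 were not called. Of 9 tested blood, stromal and vascular genes of placenta, 4 rose and 0 fell.

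Of 15202 genes tested, 1527 rose and 884 fell, and 1073 rose and 267 fell by at least 2-fold. Library totals alone gave 1671 higher and 594 lower, so that 73.8% of the calls were higher in place of 63.3%. Scaling on ribosomal protein genes moved the median log2 fold change of all 15202 tested genes from -0.004 to 0.167. It gave 1175 higher and 128 lower, or 90.2% higher. The GC offset, added after the results were seen, gave 2067 higher and 1791 lower, or 53.6% higher, and DESeq2 1347 and 1188, or 53.1% higher. Without untreated replicate 2, 953 rose and 407 fell. Without untreated replicate 1 and without triptolide replicate 3, 529 and 457 fell. The groups did not overlap in 36.7% of tested genes, where chance gives 10%. All rises and falls given here are relative to the other genes of a library, so a change in total mRNA per cell would not show.

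**Figure D1:**
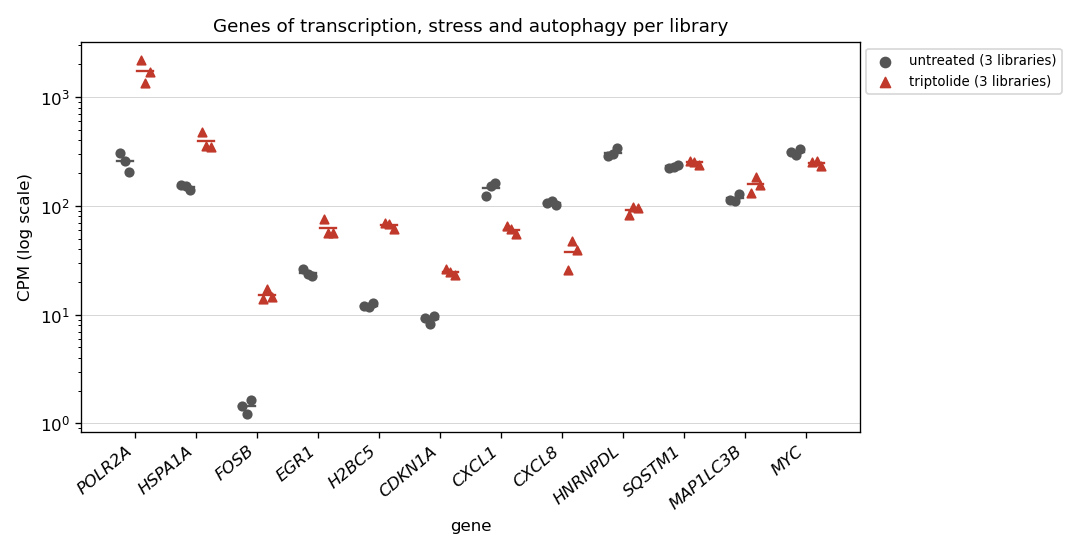
CPM of 12 genes on a log axis in the 3 untreated libraries (circles) and the 3 triptolide libraries (triangles), with a line at each group's mean. POLR2A averaged 257 CPM in untreated and 1758 CPM in triptolide libraries, while SQSTM1 averaged 231 and 251 CPM.

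Among 37 tested genes for RNA polymerase II, TFIIH and elongation factors, 4 rose and 2 fell, with the same counts adjusted over the list alone, and the list did not stand apart by camera (adjusted p = 0.898). HEXIM2, whose product restrains the elongation factor P-TEFb, rose 2.48-fold to 6.17 ± 0.45 CPM. MEPCE, the capping enzyme of 7SK RNA, rose 1.75-fold, with an adjusted p of 0.0535 without untreated replicate 2. ERCC3, which encodes the XPB subunit, stood at 109 ± 0.49 CPM untreated and 118 ± 2.86 CPM with triptolide (adjusted p = 0.633).

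Immediate early and short-lived transcripts were higher as a list by camera (adjusted p = 0.0251), which was lost with an estimated correlation (adjusted p = 0.865). Of 42 tested, 11 rose and 2 fell, and 15 rose and 3 fell adjusted over the list alone. EGR1 rose 2.6-fold to 62.9 ± 11.2 CPM and ATF3 3.01-fold to 12.6 ± 1.37 CPM, while ID3 fell 1.96-fold to 166 ± 14.2 CPM. The list's call was also lost without triptolide replicate 1 (adjusted p = 0.183) and without untreated replicates 1, 2 or 3 (adjusted p = 0.0569, 0.0655 and 0.0509), and with the GC offset (adjusted p = 0.158). MYC stood at 313 ± 17.9 and 248 ± 14.6 CPM (adjusted p = 0.148, and 0.0227 with the GC offset), and MCL1 at 331 ± 29.7 and 346 ± 46.6 CPM (adjusted p = 0.834). Of 25 genes for MAPK feedback and output, 4 rose and 2 fell, and 4 and 3 did so adjusted over the list alone. IER3 rose 2.03-fold and EPHA2 1.88-fold.

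Replication-dependent histones were higher as a list (camera adjusted p = 0.0168, and adjusted p = 0.865 with an estimated correlation). Of 34 tested, 12 rose and 2 fell, and 15 rose and 3 fell adjusted over the list alone. H2BC5 rose from 12.1 ± 0.57 to 66.2 ± 4.29 CPM and H4C8 rose 4.9-fold, while the linker histone gene H1-2 fell 2.45-fold. These mRNAs mostly end without a poly(A) tail, these libraries were poly(A)-selected, and reads of the histone family can fit several copies. Without untreated replicates 1 or 2 or triptolide replicate 2 the list's adjusted p was 0.0831, 0.0655 and 0.0873, and with the GC offset it was 0.0789.

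In the heat shock response, 6 of 29 tested genes rose and 1 fell, and 7 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.548). HSPA6 rose 5.05-fold to 5.02 ± 1.5 CPM and the co-chaperone gene DNAJA4 2.12-fold. HSPA8, the constitutive family member, fell 1.67-fold from 3592 ± 308 CPM, with an adjusted p of 0.0507 without triptolide replicate 3 and 0.0771 with ribosomal protein scaling. HSPA1B, whose reads overlap those of its near-identical copy HSPA1A, rose 1.76-fold, and its adjusted p was 0.1 without untreated replicate 1, 0.077 without untreated replicate 2 and 0.0752 without triptolide replicate 3. HSF1 stood at 113 ± 10.7 and 114 ± 27.1 CPM (adjusted p = 0.969).

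Of 29 tested NF-kB targets, 5 fell and 1 rose, and 8 fell and 1 rose adjusted over the list alone (camera adjusted p = 0.262, and lower with no low-count filter at an adjusted p of 0.0086, while the adjusted p was 0.865 with an estimated correlation). BIRC3, an inhibitor of apoptosis, fell 2.73-fold from 22.8 ± 3.69 to 8.28 ± 2.45 CPM. Among 11 anti-apoptotic genes 3 fell, namely BIRC3, BIRC2 and XIAP, and 4 fell and 1 rose adjusted over the list alone (camera adjusted p = 0.262). BIRC2 fell 1.85-fold and XIAP 1.67-fold, and without untreated replicate 2 their adjusted p was 0.0544 and 0.15. XIAP also did not pass without untreated replicate 1 or triptolide replicates 1 or 2 (adjusted p = 0.104, 0.118 and 0.108), with library totals alone (0.107) or with a mean of at least 5 CPM (0.109). With ribosomal protein scaling BIRC2 and XIAP had adjusted p-values of 0.219 and 0.42. BIRC5 stood at 270 ± 28 and 280 ± 26.3 CPM (adjusted p = 0.855). Of 28 pro-apoptotic genes, 5 rose and 1 fell, and 9 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.548). BIK rose 3.16-fold to 2.23 ± 0.34 CPM. Of 28 p53 targets, 4 rose and 1 fell, and 5 and 1 did so adjusted over the list alone (camera adjusted p = 0.534). The cell cycle inhibitor CDKN1A rose 2.72-fold to 24.8 ± 1.6 CPM and GDF15, which placenta also expresses, 4.01-fold.

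Of 42 tested genes of the macroautophagy machinery, 2 rose and 0 fell over all genes and adjusted over the list alone (camera adjusted p = 0.78). At an unadjusted p under 0.05 in edgeR, 6 were higher and 1 lower, and DESeq2 and limma-voom each called 2 higher and 0 lower. ATG2A, a lipid transfer protein of the growing autophagosome, rose 2.14-fold to 83.9 ± 25.7 CPM (adjusted p = 0.0046). ATG4D, a protease that processes LC3-family proteins, rose 1.86-fold, and without untreated replicates 1 or 2 its adjusted p was 0.0636 and 0.0684. The cargo receptor SQSTM1 stood at 231 ± 6.74 and 251 ± 12.9 CPM (adjusted p = 0.609) and MAP1LC3B at 118 ± 8.5 and 158 ± 26.8 CPM (adjusted p = 0.113, and 0.0258 without triptolide replicate 1). BECN1 stood at 57.5 ± 5.28 and 55.9 ± 2.37 CPM, ULK1 at 30.7 ± 2.5 and 37.4 ± 9.64 CPM, ATG5 at 35.7 ± 3.61 and 34.8 ± 7.62 CPM, and ATG7 at 26.2 ± 0.84 and 28.8 ± 1.37 CPM, and none of the 4 passed the test. Of 45 lysosome genes, 2 rose and 1 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.33). SMPD1 rose 1.55-fold, with adjusted p-values of 0.101, 0.145 and 0.0567 without untreated replicates 1 or 2 or triptolide replicate 2. The protease gene CTSC fell 1.62-fold from 682 ± 26 to 420 ± 9.91 CPM, with an adjusted p of 0.0609 with the GC offset. With ribosomal protein scaling SMPD1 and CTSC had adjusted p-values of 0.0769 and 0.164. Among genes with a mean of at least 5 CPM the lysosome list was higher (adjusted p = 0.0119), while over all tested genes its adjusted p was 0.865 with an estimated correlation.

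Of 49 tested structural genes of the extracellular matrix, 14 fell and 6 rose, and 15 fell and 8 rose adjusted over the list alone. The list's median log2 fold change was -0.03 and its mean -0.52 (camera adjusted p = 0.152). COL1A1 (ENSG00000108821) fell 21.8-fold, from 61.1 ± 12.1 to 2.83 ± 0.5 CPM, and THBS1 (ENSG00000137801) 64.9-fold, from 28.6 ± 6.53 to 0.42 ± 0.15 CPM. FN1 (ENSG00000115414) fell 8.31-fold, from 180 ± 45.8 to 21.7 ± 12.2 CPM, and SPARC 5.97-fold. POSTN had 441 counts in the untreated and 3 in the triptolide libraries, a ratio of 165 with a 95% interval from 56 to 803. TNXB, which has a pseudogene copy that can share reads, rose 10.5-fold to 14.7 ± 5.93 CPM and COL6A3 2.49-fold to 326 ± 59.6 CPM. Of 58 tested genes on the list of fibroblast and mesenchymal genes, which holds COL1A1, FN1 and others of these genes, 27 fell and 6 rose, and the counts were 31 and 7 adjusted over the list alone. This list was written after the values of 16 of the 58 had been seen, and of the other 42, 12 fell and 5 rose. Without the genes of the placental, blood and fibroblast lists, the structural list lay on the higher side (camera adjusted p = 0.598). That step takes out COL1A1, FN1, THBS1, POSTN, SPARC and other fallen members, so it removes the fall by construction and decides nothing. Without triptolide replicate 1 the structural list was lower (adjusted p = 0.0303), while with all libraries its adjusted p was 0.896 with an estimated correlation.

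Of 38 tested remodelling enzymes of the matrix, 6 rose and 7 fell, and 7 rose and 8 fell adjusted over the list alone (camera adjusted p = 0.898). ADAM12, also abundant in placenta, rose 9.27-fold to 10.7 ± 1.08 CPM, and the urokinase receptor gene PLAUR rose 2.18-fold to 97.7 ± 22.1 CPM. The gelatinase gene MMP2 fell 4.09-fold to 1.22 ± 0.41 CPM and MMP3 2.58-fold. Mesenchymal and EMT markers were lower as a list (camera adjusted p = 0.0114, and adjusted p = 0.462 with an estimated correlation), with 6 fallen and 1 risen of 17 tested, and 6 and 2 adjusted over the list alone. CDH2 had 104 counts in the untreated and 0 in the triptolide libraries, at least 38.9-fold lower. The transcription factor gene SNAI1 rose 2.53-fold. Without the placental, blood and fibroblast list genes the camera adjusted p of the EMT list was 0.397, a step that takes out the fallen members CDH2 and FN1 by construction. With the GC offset its adjusted p was 0.0637, and among genes with a mean of at least 5 CPM it turned to the higher side (adjusted p = 0.992). Of 22 TGF-beta targets, 4 fell and 1 rose, and 5 and 3 did so adjusted over the list alone. TGFBI fell 2.87-fold to 17.2 ± 1.64 CPM. Of 23 YAP/TAZ targets, 5 fell and 3 rose, and 5 and 4 did so adjusted over the list alone. NUAK2 fell 2.22-fold. Of 33 integrin and focal adhesion genes, 2 rose and 2 fell, both over all genes and adjusted over the list alone, and PTK2B rose 2.68-fold. These 3 lists did not pass camera (adjusted p = 0.304, 0.42 and 0.941).

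Under the rule for named genes, the 6 largest rises were in genes known from placenta. CSH1 (ENSG00000136488) and CSH2 (ENSG00000213218), near-identical genes of placental lactogen that can share reads, rose from 4.92 ± 0.13 to 430 ± 175 CPM and from 2.22 ± 0.5 to 157 ± 32.5 CPM. KISS1 (ENSG00000170498) rose 80.9-fold to 23 ± 5.78 CPM, CGA, the common subunit of glycoprotein hormones, 27.3-fold to 11.8 ± 0.87 CPM, and PSG1 37.8-fold. AOC1 (ENSG00000002726), the diamine oxidase gene, rose 141-fold, a log2 fold change of 7.14 that was 6.53 without triptolide replicate 2. It had 203, 432 and 61 counts in triptolide replicates 1, 2 and 3 and 4 counts in the untreated libraries together. On the list of placental trophoblast genes, written after the top of the results had been seen, 41 of 48 tested genes rose and 1 fell, with the same counts adjusted over the list alone. The values of 29 of the 48 had been seen by then, and of the other 19, 14 rose and 1 fell. On that of blood, stromal and vascular genes of placenta, 4 of 9 rose and 0 fell, and 5 rose and 1 fell adjusted over the list alone, with 1 risen of the 6 not seen before. HBA2, an alpha globin gene, had 8 counts in the untreated and 282 in the triptolide libraries. Of 11 stromal, endothelial and immune markers fixed in advance, 3 rose and 2 fell, and 4 rose and 3 fell adjusted over the list alone (camera adjusted p = 0.548). CSF1R, a macrophage receptor gene, rose 5.53-fold to 1.15 ± 0.07 CPM, and the smooth muscle actin gene ACTA2 fell 2.56-fold.

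**Figure D2:**
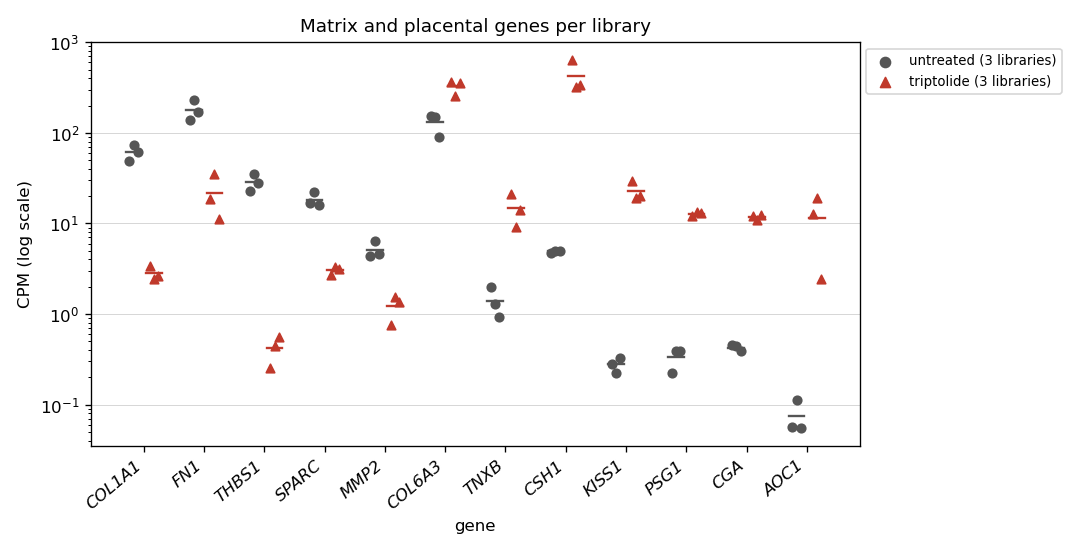
CPM of 12 matrix and placental genes on a log axis in the 3 untreated libraries (circles) and the 3 triptolide libraries (triangles), with a line at each group's mean. COL1A1 averaged 61.1 CPM in untreated and 2.83 CPM in triptolide libraries, and CSH1 averaged 4.92 and 430 CPM.

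Genes of ribosome biogenesis and MYC targets were lower as a list (camera adjusted p = 2.4e-06, and adjusted p = 0.118 with an estimated correlation). Of 38 tested, 8 fell and 0 rose, and 15 fell and 0 rose adjusted over the list alone. PPAN fell 1.96-fold and GAR1 1.77-fold, to 6.05 ± 0.43 and 17.4 ± 3.57 CPM, and neither passed with scaling on ribosomal protein genes. Ribosomal proteins were lower as a list (camera adjusted p = 0.00145, and adjusted p = 0.896 with an estimated correlation), with a median log2 fold change of -0.23. Of 79 tested only RPL17 fell, by 1.62-fold, and 0 rose, and 0 passed adjusted over the list alone. RPL17 had adjusted p-values of 0.06, 0.0877 and 0.0627 without untreated replicates 2 or 3 or triptolide replicate 3, and of 0.0556, 0.337 and 0.0692 with library totals, ribosomal protein scaling and a mean of at least 5 CPM. The list's adjusted p was 0.288 without untreated replicate 3 and 0.0647 without triptolide replicate 3. Nuclear-encoded oxidative phosphorylation genes were lower as a list (camera adjusted p = 0.043, and adjusted p = 0.896 with an estimated correlation), with 1 fallen and 0 risen of 44 and 0 adjusted over the list alone. That gene, NDUFV2, had 0.94 ± 0.33 and 0.31 ± 0.16 CPM. Its adjusted p was 0.14, 0.109, 0.0945 and 0.0855 without untreated replicates 2 or 3 or triptolide replicates 1 or 3, and 0.0544, 0.127 and 0.0809 with library totals, ribosomal protein scaling and DESeq2. The list's adjusted p was 0.548 without untreated replicate 3 and 0.249 without triptolide replicate 3. It was 0.281 with a mean of at least 5 CPM, 0.0789 with the GC offset and 0.0616 with ribosomal protein scaling. Of 13 mitochondrially encoded genes, 0 passed in edgeR over all genes or adjusted over the list alone (camera adjusted p = 0.548). At an unadjusted p under 0.05 there was 1, and DESeq2 and limma-voom called 0. They took 5.44 ± 0.44% of untreated and 6.4 ± 1.37% of triptolide counts (exact permutation p = 0.3). Ribosomal protein genes took 8.54 ± 1.59% and 7.81 ± 0.73% (exact permutation p = 0.7), and the 50 most abundant genes 18.7 ± 1.35% and 18.8 ± 1.29% (exact permutation p = 1).

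G2/M and mitosis genes were lower as a list (camera adjusted p = 0.0303, and adjusted p = 0.865 with an estimated correlation). Of 44 tested, CCNB1 alone fell and 0 rose, and the counts adjusted over the list alone were the same. CCNB1, the cyclin of mitotic entry, fell 1.62-fold from 530 ± 50.2 to 326 ± 39.3 CPM, with adjusted p-values of 0.0617 without triptolide replicate 3, 0.0549 without untreated replicate 2 and 0.183 with ribosomal protein scaling. The list's adjusted p was 0.28 without triptolide replicate 1 and 0.0568 without untreated replicate 2. It was 0.126 with the GC offset, 0.101 with a mean of at least 5 CPM and 0.0586 with ribosomal protein scaling. Of 45 genes for G1/S and DNA replication, 1 rose and 2 fell, and 0 and 1 did so adjusted over the list alone (camera adjusted p = 0.434). RFC4, a subunit of the clamp loader, fell 1.71-fold, with an adjusted p of 0.197 with ribosomal protein scaling.

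In glycolysis and hypoxia, 5 of 33 tested genes rose and 0 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.355). NDRG1 rose 2.46-fold to 84.7 ± 4.74 CPM. In endoplasmic reticulum stress and ATF4 targets, 1 of 36 rose and 2 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.941). ASNS, asparagine synthetase, rose 3.14-fold. DDIT4 fell 1.8-fold, with an adjusted p of 0.139 with ribosomal protein scaling. Of 22 genes of sterol biosynthesis, 1 rose and 0 fell, also adjusted over the list alone (camera adjusted p = 0.898). Of 26 NRF2 targets, 3 rose and 1 fell, and 3 and 2 did so adjusted over the list alone (camera adjusted p = 0.78). Of 29 interferon-stimulated genes, 2 rose and 2 fell, both over all genes and adjusted over the list alone (camera adjusted p = 0.941). Of 11 ductal and epithelial markers, 2 rose and 1 fell, and 2 and 2 did so adjusted over the list alone (camera adjusted p = 0.898). S100P, which placenta also expresses, rose 3.24-fold and CLDN4 2.22-fold. Of the pancreatic acinar and endocrine markers, 1 was tested, CEL, at 2.46 ± 0.64 and 3.77 ± 0.88 CPM (adjusted p = 0.148), and 1 rose adjusted over the list alone.

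**Figure D3:**
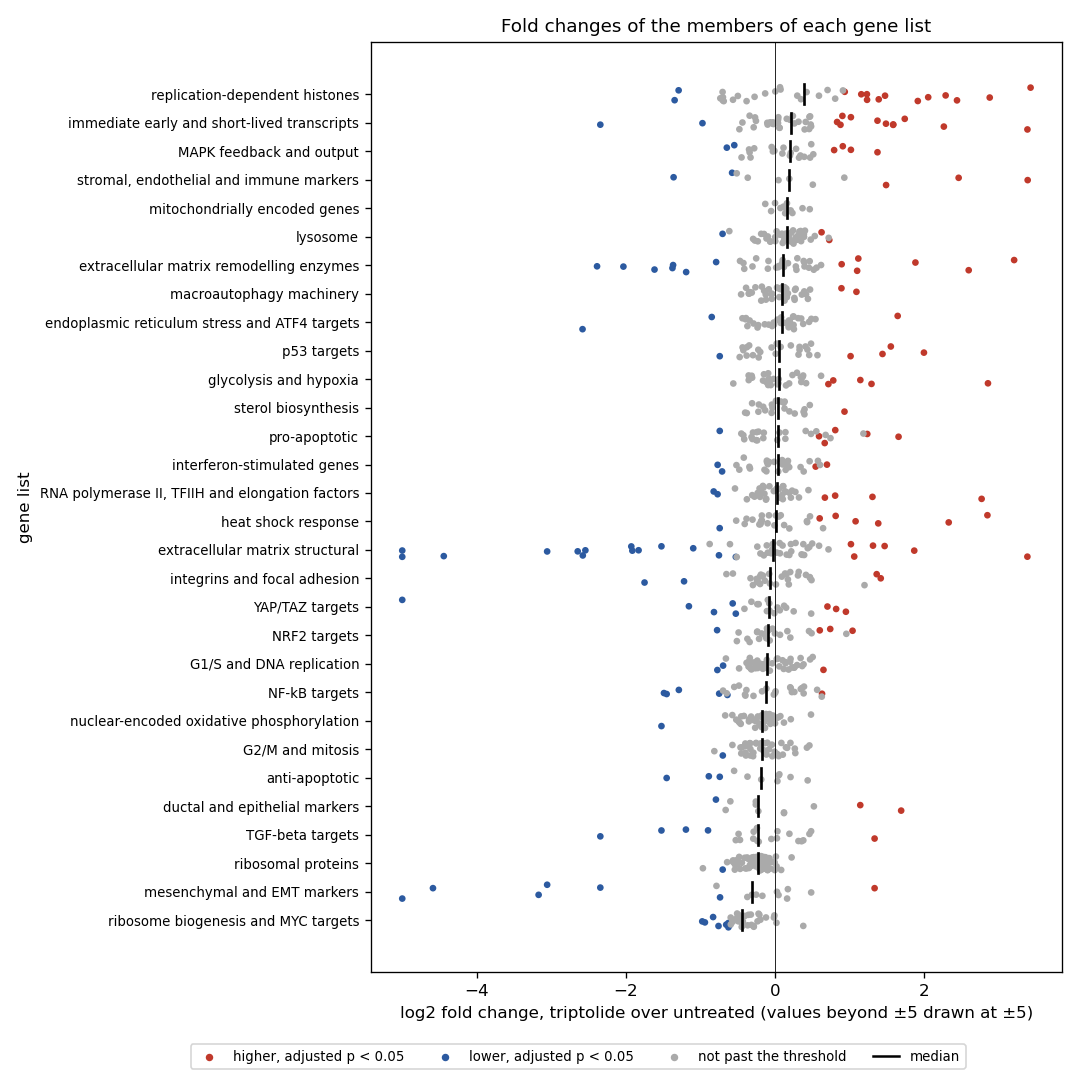
Log2 fold change of triptolide over untreated for the tested members of each of 30 gene lists, with red points for genes that rose, blue for genes that fell, grey for the rest and a black line at the list's median. Values beyond the axis limit are drawn at it. The medians run from -0.44 for ribosome biogenesis and MYC targets to 0.39 for replication-dependent histones.

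In all, camera called 7 of the 30 lists, 2 higher and 5 lower, and with an estimated correlation it called 0, with 2 at an unadjusted p under 0.05, while fry called 8. Without untreated replicate 2, and without untreated replicate 3, it called 4. With the GC offset it called 2, ribosome biogenesis and MYC targets and ribosomal proteins, so that the other 5 were lost.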

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

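The tests with a GC offset and without the placental, blood and fibroblast list genes were chosen after the results were seen. Leaving out these list genes takes out many fallen members of the structural matrix and EMT lists. What these 2 lists show without them is thus largely set by construction. RLE size factors, DESeq2 and limma-voom kept each count within 1.5 times, with 1347 higher and 1188 lower under DESeq2. The lower count was 128, and the count at least 2-fold lower 112, with scaling on ribosomal protein genes. A mean of at least 5 CPM, which leaves 10290 genes, gave 584 higher and 336 lower, and 263 and 78 by at least 2-fold. The GC offset gave 1791 lower and 2 lists called. A test against a fold of 1.5, a stricter hypothesis, left 608 and 135 genes. With an estimated correlation 0 lists were called. With 1 library left out, the higher count ran from 953 to 1580, the lower from 407 to 1034 and the lists called from 4 to 6. Of 113 named genes past the threshold, 75 stayed past it with each library left out. Across all alternatives, calls of named genes were lost 189 times and gained 2 times, and 1661 comparisons kept their direction and side of the threshold. Of these losses 38 came with ribosomal protein scaling and 32 without untreated replicate 2.

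List results are adjusted p-values. The structural matrix list was lower at 0.0155 with ribosomal protein scaling and 0.0086 with no low-count filter, and higher at 0.992 with a mean of at least 5 CPM and 0.598 without the placental, blood and fibroblast list genes. With 1 library left out it ran from 0.0303 to 0.427. Matrix remodelling enzymes turned lower at 0.981 with ribosomal protein scaling and 0.508 with no filter, were higher at 0.0293 with a mean of at least 5 CPM, and ran from 0.786 to 0.991 with 1 library left out. Over all tested genes their adjusted p by camera with an estimated correlation was 0.964. The lysosome list was higher at 0.0119 with that mean and 0.05 with fry. NF-kB targets were lower at 0.0086 with no filter. With fry, which does not compare a list with other genes, p53 targets (0.0286) and pro-apoptotic genes (0.0352) were higher and TGF-beta targets (0.0352) lower, while G2/M (0.266), ribosomal proteins (0.444) and oxidative phosphorylation (0.482) did not pass. With no filter, directions also turned for macroautophagy (0.911), RNA polymerase II and elongation factors (0.633), endoplasmic reticulum stress (0.649), sterol biosynthesis (0.799) and ductal markers (0.591). With a mean of at least 5 CPM they turned for integrins (0.473), TGF-beta targets (0.982), NRF2 targets (0.992), interferon-stimulated genes (0.295), ductal markers (0.919) and EMT markers (0.992). With fry they turned for integrins (0.672), interferon-stimulated genes (0.747) and ductal markers (0.944), and with the GC offset for integrins (0.997). With 1 library left out, lists that turned ran from 0.869 to 0.989 for RNA polymerase II, 0.866 to 0.972 for endoplasmic reticulum stress, 0.869 to 0.988 for sterol biosynthesis, 0.781 to 0.951 for interferon-stimulated genes, 0.556 to 0.988 for integrins, 0.267 to 0.951 for mitochondrially encoded genes and 0.592 to 0.989 for ductal markers.

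Genes that changed sign were not past the threshold. The log2 fold change of ATG5 was 0.037, 0.151, 0.046 and 0.128 with library totals, ribosomal protein scaling, a mean of at least 5 CPM and the GC offset, and that of BECN1 was 0.021, 0.112, 0.041 and 0.007. HSF1 was at -0.131 with the GC offset, -0.021 with DESeq2 and -0.01 with limma-voom, and BIRC5 at -0.02 with the GC offset. With 1 library left out, HSF1 ran from -0.18 to 0.12, BECN1 from -0.119 to 0.014, BIRC5 from -0.029 to 0.117, MCL1 from -0.02 to 0.184, ATG5 from -0.182 to 0.134, MT-CO1 from -0.044 to 0.226 and MT-CO3 from -0.025 to 0.313. Where no construction of the alternative shows it, the cause was not tested.

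Replicate numbers are shared by the groups, but same-numbered libraries correlated at 0.03, -0.04 and -0.44 in their deviations, so the numbers do not pair them. With a replicate block 1523 genes were higher and 856 lower, the structural matrix list was lower (0.0174), endoplasmic reticulum stress turned lower (0.942), SMPD1 did not pass (0.0629) and HSF1 was at -0.007. Depth limits genes near the floor of 3 counts, and the simulated 1.5-fold changes were mostly missed.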

Other observations

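Tests on the placental genes, on the fibroblast profile, on short-lived transcripts, on abundance and with the GC offset were chosen only after the results were seen. For GC content, olfactory receptor genes, untreated replicate 2 and splits of the libraries, the bound was set before the value it was held to was known. Antisense and lincRNA genes rose more often than protein-coding genes: 206 of 759 antisense genes (27.1%) and 145 of 610 lincRNA genes (23.8%) rose, against 971 of 12345 protein-coding genes (7.87%). Together they rose in 25.6% of 1369, with a median log2 fold change of 0.49, and 1369 coding genes matched on abundance in 19.8%, with a median of 0.26. Fisher's exact tests against all protein-coding genes, unmatched, gave adjusted p-values of 1.18e-50 and 2.14e-30, over genes, which are not independent replicates. Antisense and lincRNA genes took 0.56 ± 0.02% of untreated and 0.69 ± 0.06% of triptolide counts (SD, n = 3, exact permutation p = 0.1, the smallest possible). Without a stated strand setting, reads of antisense genes cannot be told from those of their partners. Other gene types also rose more often than protein-coding genes. Examples were bidirectional promoter lncRNA (46.4% of 28), processed transcripts (24.5% of 139) and transcribed unprocessed pseudogenes (17.65% of 187). Processed pseudogenes (5.19% of 559) and sense intronic genes (4.48% of 67) did not. On the list of hnRNP, SR and core spliceosome genes, 13 of 60 tested genes fell and 0 rose, and 21 fell adjusted over the list alone. Of these 13 fallen genes 11 had been seen when the list was written, and of the 49 genes not seen 2 fell and 0 rose. HNRNPA1 had a log2 fold change of -1.3 ± 0.17 (SE) and SRSF1 of -1.43 ± 0.29, while SRSF5 was at 0.06 ± 0.15. The last 3 genes were chosen after their values were seen.

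The first pattern is the rise of placental genes. Reads shared among near-identical copies are argued against as the whole cause, though within the CSH and PSG families such sharing stays open. Taken were 25 trophoblast genes outside multi-copy families, not seen when the list was written and with at least 10 counts. Of these, 19 (76%) were above every untreated library in every triptolide library. Random labels would give 5%, but over all tested genes the groups did not overlap in 36.7%, counting both directions. The 5% is thus a low baseline, also for the shares below. A candidate explanation is RNA from placental tissue in the triptolide libraries: with the multi-copy families included, 28 of 34 unseen trophoblast genes with at least 10 counts (82.4%) were above in this way, and 29 of 37 (78.4%) with no such minimum, and CSH1, the most abundant, reached 430 CPM. Of 21 genes on the blood, stromal and vascular list 10 were above in the same way, and 7 of the 18 not seen when it was written. No count minimum was set for this list. Of these 7, HBG1, AHSP, ALAS2 and EGFL6 had only 4, 6, 14 and 15 counts over the triptolide libraries together. The others, PECAM1, VWF and CD14, had 58, 52 and 212. Within the triptolide group, shares of counts were compared as replicate 2 over replicate 3. The median ratio was 4.28 (2.44 to 7.31) for 8 decidual and extravillous genes. For 12 syncytiotrophoblast genes it was 0.908 (0.677 to 1.21). Both sets were picked by hand, with TIMP3 taken from the fibroblast list, and other listed trophoblast genes were left out. Among those left out, PAPPA2 had 101 and 93 counts in triptolide replicates 2 and 3, and TFPI2 221 and 200. XAGE3 had 16 and 7, and INSL4 3 and 13. The proportions of the picked genes differed between these libraries, and the ranges do not describe placental genes in general. This difference was not tested. Induction in the cells by triptolide cannot be told apart from RNA of placental tissue, because the treatment and the libraries form the same split.

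The second pattern is the fall of matrix genes. Loss of short-lived transcripts stays open. The list of immediate early and short-lived transcripts had a median log2 fold change of 0.22, with 11 of 42 tested genes risen and 2 fallen. A rise of inducible genes such as FOSB and EGR1 can hide a loss of others, so this median cannot decide. Untreated replicate 2 alone is argued against for the genes at least 4-fold lower: without it, they had a median log2 fold change of -2.75. These genes were called with all libraries, which by itself disfavours genes high in a single library. RNA from fibroblast-like cells in the untreated libraries stays open, with values on both sides. Untreated replicate 2 was the highest untreated library for 27 of 38 genes at least 4-fold lower (71.1%). It was the highest for 59 of 229 genes 2-fold to 4-fold lower (Fisher's exact p = 2.13e-07, over genes, which are not independent replicates). But of 42 fibroblast list genes not seen when the list was written, 12 fell, 5 rose and 25 were not called. Of the 18 of these with a mean under 5 CPM over all libraries, 10 fell, 3 rose and 5 were not called. A fall caused by triptolide in the cells themselves stays open and untested.

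The third pattern is the rise of antisense and lincRNA genes. GC content is argued against as the cause of the single calls, since 98% of the 351 that rose were still called with the GC offset. This share does not set them apart, as 1504 of all 1527 genes that rose also stayed called. Their excess over coding genes was not tested with the offset, so for the excess GC content stays open. Low abundance stays open: the matched coding genes rose in 19.8% against 25.6%, and had a median log2 fold change lower by 0.23. The 95% bootstrap interval, from 0.17 to 0.31, reaches below the bound of 0.2. It resampled genes, which are not independent replicates, with the libraries and the matched draw held fixed, so it does not measure spread between libraries. Genomic DNA or other background also stays open. With counts drawn down to 16302961 per library, 23829 ± 115 genes were detected in untreated and 25484 ± 729 in triptolide libraries (exact permutation p = 0.1, the smallest possible). The summed CPM of 120 olfactory receptor genes was higher in every triptolide library, by at least 5.39, but without the 3 most abundant, a check added after the values were seen, triptolide libraries had 1.72 to 3.81 CPM and untreated libraries 1.02 to 1.84.

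The 6 libraries can be split in 10 ways, too few for a share under 0.05. Each split but the real one mixes untreated and triptolide libraries on both sides. Any large difference between the groups, whatever its cause, then leaves few gene calls, so the contrast says nothing about the cause. The real split gave 1527 higher and 884 lower genes, and 1073 and 267 by at least 2-fold, where the highest other split gave 1 in each case, so 1 of the 10 splits, the real one, gave as many. It gave 7 lists called by camera, and another split gave 9, so 2 of the 10 gave as many.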
